A study of Homo sapiens with 12 samples.

How the data were processed

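Expression was measured in H1 cells, an established human embryonic stem cell line, on 12 Illumina bead arrays. Per the labels' protocols, cells were transfected with Fugene the day after seeding, either with an shRNA against OCT4 or with an shRNA against luciferase as the negative control. They were harvested 2 or 3 days after transfection, RNA was extracted with Trizol and treated with DNase I, and biotin-labelled cRNA was hybridised. Groups and replicate numbers were taken from the sample titles. This gave 4 groups of 3 arrays, called knockdown and control at day 2 and day 3. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

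The values analysed were the deposited probe intensities on a linear scale, 1 per probe and array for 48803 probes, without normalisation or background subtraction that the file headers record. The deposited table also gives a detection p-value for each probe and array, in steps of 1 in 759. The scanner and its software are not given in the sources used here. A separate deposited table holds processed values made by the authors. Set against the intensities of the same arrays, these were log2 intensities less 1 constant per array and 1 baseline per probe, with a remainder between arrays of SD 2.56e-07. Their column medians lay between -0.0146 and 0.0136. Scale and direction were settled by this comparison, whereas the samples over which the baseline was taken stayed unknown (the baseline differed from the median of the 12 arrays by an SD of 0.0733). The authors' log2 values served only as an alternative.

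Background was corrected with neqc of limma 3.58.1 in R 4.3.3, using the detection p-values in place of negative control probes, followed by an offset of 16, quantile normalisation and log2. Probes with a detection p under 0.01 on at least 3 of the 12 arrays were kept, 15407 in all. Gene names came from GEO's annotation of the array, which names exactly 1 gene for 28098 probes, several for 13 and none for 20692. Of the 28098 probes, 28059 were matched by Entrez identifier to NCBI RefSeq's gene table of the human assembly GRCh38.p14, and 0 symbols changed. Of the kept probes, 13347 had 1 gene and 2060 had no name. The brightest kept probe stood for each gene, giving 10506 genes. Among 2373 genes with several kept probes, none at day 2 and 4 at day 3 had probes called in opposite directions. Probes can cross-hybridise with close relatives. POU5F1 has near-identical pseudogenes and CST1 has close paralogs, and whether their probes tell these apart was not tested.

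All 12 arrays entered 1 limma fit with a mean per group and no block, which left 8 residual degrees of freedom, to which the moderated spread added 5.2. Contrasts were knockdown minus control at day 2 and at day 3, the difference between these effects, their average, and control day 3 minus control day 2. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons of the days share no array, while the control comparison shares arrays with both knockdown comparisons and was not correlated with them. Where a gene was not detected on any of a group's 3 arrays, its fold is given as a lower bound. The bound sets the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value of a detected probe (log2 5.69 to 6.16). No fold is given where the probe was undetected in both groups.

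The numbers of the replicates were checked for pairing through the correlation, across genes, of the arrays' deviations from their group means. For control and knockdown at day 3 these were 0.483, 0.389 and 0.738 for replicates 1, 2 and 3, and for the control arrays of the 2 days 0.241, 0.214 and 0.666. For the knockdown arrays of the 2 days they were 0.22, 0.598 and 0.724. All lay over 0.1, so the numbers were taken to pair the arrays of these comparisons, although no label says what a number marks. A fit with the replicate number as a block was run for every comparison. The fit reported has no block, so its p-values leave this pairing out. With the block more genes were called, 4536 in place of 3114 at day 3 and 756 in place of 243 for the difference between days. In the control arrays it was 450 in place of 26.

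Altogether 24 gene lists were chosen before the data were examined: pluripotency, naive pluripotency, trophoblast, amnion, endoderm, mesoderm and primitive streak, neuroectoderm, stromal and fibroblast markers, epithelial markers, mesenchymal transition, targets of TGF-beta and Nodal, BMP, WNT, and FGF and ERK signalling, DNA replication, mitosis, interferon response, p53 targets, the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, HOX genes, and chromatin and DNA methylation. POU5F1 was left out of every list, and some genes stand in several. Members were counted by their call over all genes and adjusted over the list alone. Each list was set against all other genes with camera of limma at a correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation.

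Genes were named by a rule chosen at the same time. It took POU5F1, the 10 largest rises and the 10 largest falls of each knockdown comparison whose groups of 3 arrays did not overlap, and up to 4 members of each list with the smallest adjusted p. It added NANOG, SOX2, CDX2, GATA3, GATA6, SOX17, TBXT and PAX6 whatever their p, and the 5 largest changes in each direction for the difference between days and for the control. CDX2 and PAX6 were detected on 0 arrays and GATA6 on 2, both knockdown day 3 arrays, so these genes were not tested.

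Alternatives were no background correction, normexp with an offset of 50, median scaling, the authors' log2 values, no detection filter, detection on all 12 arrays, the mean of a gene's probes, probes tested one by one, the replicate block, only the 2 groups compared, array weights, a trended and robust prior, adjusted p under 0.01, a change of at least 2-fold, and each array left out in turn. A chip block was not run, because no chip is given in the sources used here. Other splits of the arrays were refitted too.

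The fit was tested on simulated data with 200 changed genes among 10506. At day 2 it recovered 14 of 67 genes changed by 0.5 on the log2 scale, 45 of 67 changed by 1 and 64 of 66 changed by 2. At day 3 it recovered 12 of 67, 52 of 67 and 66 of 66. False calls were 5 of 128 at day 2 and 6 of 136 at day 3. In a simulation with 1 list shifted by 0.5, camera called that list and 0 of the lists that shared no member with it. The simulated noise was independent between genes and arrays, without correlated genes or shifts between replicate numbers. These simulations therefore do not give the rate of false calls in the real data. Figures were drawn with matplotlib 3.10.9.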

Results

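Messenger RNA levels were compared in H1 human embryonic stem cells that received an shRNA against OCT4 or an shRNA against luciferase, an enzyme that human cells do not make. The study's stated purpose was to find mRNAs targeted by OCT4, a transcription factor of pluripotent cells encoded by POU5F1. The labels name no other OCT4 shRNA, so effects of OCT4 loss cannot be told from other effects of this shRNA. The 12 arrays formed 4 groups of 3, knockdown and control at 2 and at 3 days after transfection, and this number limits the precision. Between 13343 and 14969 of 48803 probes were detected per array, with median intensities of 69.6 to 71.8 and brightest probes of 42230 to 59496. Arrays of 1 group correlated at 0.988 to 0.994 across probes. Over the tested genes, the first principal component held 56.4% of the variance and separated knockdown from control arrays. The second held 17.2% and separated the replicate 3 array of every group from the other arrays of that group.

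POU5F1, the targeted gene, lay lower on every knockdown array than on any control array. At day 2 its normalised log2 intensity was 12.92 ± 0.22 (SD, n = 3) in control and 10.69 ± 0.34 in knockdown arrays, a change of -2.23 (SE 0.19, limma adjusted p = 6.85e-06) that left 21.4% of the control level. At day 3 the levels were 13.21 ± 0.11 and 10.25 ± 0.29, a change of -2.96 (SE 0.19, adjusted p = 1.24e-07) that left 12.9%. The changes at the 2 days differed by -0.73, which did not pass the test (adjusted p = 0.244). A second POU5F1 probe, designed to another transcript, was not detected on any of the 12 arrays (log2 4.57 to 5.19) and gave no measure of the knockdown.

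**Figure D1:**
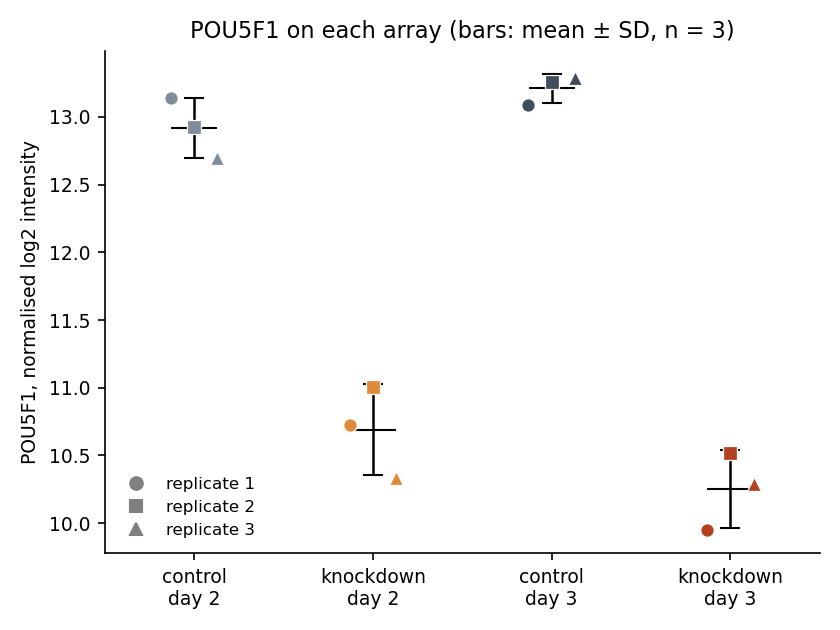
Normalised log2 intensity of POU5F1 on each of the 12 arrays by group, with horizontal lines at group means and bars of 1 SD (n = 3). The knockdown arrays lie at 9.95 to 11.01 and the control arrays at 12.69 to 13.29.

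At day 2, CST1, which encodes a secreted cystatin, rose by 5.76 on the log2 scale in knockdown (SE 0.48, adjusted p = 5.36e-06), the largest fitted rise. EOMES, a transcription factor of the primitive streak, rose by 4.0 (SE 0.36, adjusted p = 1.08e-05). DKK1 and DKK4, secreted WNT antagonists, were undetected on the control arrays and lay at least 12.7-fold and at least 17.5-fold higher in knockdown (adjusted p = 1.98e-08 and 2.47e-06, n = 3 per group). IFIT1, induced by interferon, fell by 1.85 (SE 0.17, adjusted p = 8.69e-06), and LRAT, which esterifies retinol, fell by 1.82 (SE 0.22, adjusted p = 1.21e-04). In all, 910 of 10506 genes changed, 598 higher and 312 lower in knockdown, and 359 of them changed at least 2-fold (283 higher, 76 lower).

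Further large rises at day 2 were those of WLS, a carrier needed for WNT secretion (3.79), PAPPA, a protease that cleaves IGF-binding proteins (3.47), the ligand gene BMP2 (3.42) and PKDCC (3.42). HAPLN1, a linker of the hyaluronan matrix, and LGI1 were undetected in control arrays and lay at least 6.17-fold and at least 4.75-fold higher, although another HAPLN1 probe changed by only 0.19 (adjusted p = 0.648). Another WLS probe gave 1.83 (adjusted p = 8.23e-06). Further falls were those of MYH2 (-2.0), IFIT2 (-1.69), IFIT3 (-1.61), the long noncoding RNA LNCPRESS1 (-1.57) and MRAP2 (-1.54). Another IFIT3 probe gave -1.20 (adjusted p = 0.0564). LIM2 and MSC were undetected in knockdown arrays and lay at least 1.36-fold and at least 1.95-fold lower. SOX17, an endoderm transcription factor, was undetected in control arrays and at least 1.76-fold higher in knockdown (adjusted p = 5.02e-04). SOX2 fell by 1.04 (adjusted p = 0.0218) and NANOG by 0.63 (adjusted p = 0.047), both core pluripotency factors. The NANOG call was lost in 9 of the 12 fits that left out 1 array (adjusted p = 0.0534 to 0.166). Of these fits it was kept only without knockdown day 2 replicate 2 or knockdown day 3 replicate 2 or 3. It was also lost with median scaling (0.0567), without a detection filter (0.0652) and with probes tested one by one (0.0534). The SOX2 call was lost without control day 2 replicate 2 or 3 or knockdown day 2 replicate 1 or 3 (adjusted p = 0.0503 to 0.1). GATA3 (0.69, adjusted p = 0.227) and TBXT (-0.24, adjusted p = 0.717) did not pass. However, GATA3 did without control day 2 replicate 3 (1.05, adjusted p = 0.0414) and with the replicate block (adjusted p = 0.0276, range over the alternatives 0.0276 to 0.536).

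Of the 39 measured members of the pluripotency list, 20 fell at day 2, 1 rose and 18 did not pass (24 fell and 2 rose adjusted over the list alone), with a median of -0.72 and a camera adjusted p of 3.81e-12. PRDM14 fell by 1.38, VSNL1 by 1.21, GDF3 by 1.08 and SEPHS1 by 1.06, while OTX2, which also marks anterior neuroectoderm, rose by 1.04 (another probe gave 0.87, adjusted p = 0.183). The naive pluripotency list did not pass (1 rose and 1 fell of 9, 1 and 2 adjusted over the list alone, adjusted p = 0.135), and its riser was TBX3, undetected in control arrays and at least 1.24-fold higher.

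Lists of early lineages moved upward at day 2 among their measured members. Of the list genes on the array, 18 of 31 mesoderm and primitive streak, 17 of 28 endoderm and 18 of 49 trophoblast genes were measured. For amnion it was 10 of 17 and for neuroectoderm 17 of 33. The others were detected on too few arrays to be kept, so the counts below leave out genes that stayed undetected. With undetected genes set at the detection level, list medians at day 2 moved toward 0. For mesoderm and primitive streak the median went from 1.33 to 0.44, for endoderm from 0.70 to 0.57, for trophoblast from 0.40 to 0.15 and for amnion from 0.39 to 0.18. The camera tests used the fitted values without that setting. Of 18 mesoderm and primitive streak genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 5.36e-11). Among them MSX1 lay at least 6.34-fold, LHX1 at least 4.79-fold and RUNX1 at least 1.74-fold above control arrays in which they were undetected. Of 17 endoderm genes, 10 rose and 1 fell (11 and 2 adjusted over the list alone, adjusted p = 9.02e-09), with CER1, a secreted Nodal and BMP antagonist, at 2.82, FLRT3 at 2.24 and DAB2 at 2.18. Of 18 trophoblast genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 1.26e-04), with ENPEP at least 3.30-fold and HAND1 at least 1.49-fold higher. Amnion markers did not pass as a list (4 rose and 1 fell of 10, 4 and 2 adjusted over the list alone, adjusted p = 0.135, but 0.011 without a detection filter, range over the alternatives 0.011 to 0.229), with ISL1 at 2.33 and HEY1 at -0.997. Neuroectoderm genes did not pass either (4 rose and 2 fell of 17, 5 and 3 adjusted over the list alone, adjusted p = 0.318), with FOXD3 undetected in knockdown and at least 1.33-fold lower and CDH2 higher by 0.62.

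Signalling targets shifted as well. With undetected genes set at the detection level, the day 2 median went from 1.07 to 0.31 for BMP targets and from 0.64 to 0.38 for mesenchymal transition genes. For WNT targets it went only from 1.31 to 1.28. Of 13 WNT targets, 11 rose and 0 fell at day 2 (11 and 0 adjusted over the list alone, median 1.31, adjusted p = 2.38e-16), with TNFRSF19 at 3.10 and NKD1 at least 3.73-fold higher. Of 14 BMP targets, 9 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 2.68e-07), with ID3, an inhibitor of bHLH factors, at 2.36 and BMP4 at least 1.28-fold higher. FGF and ERK targets had 6 rises and 2 falls of 18 (6 and 2 adjusted over the list alone, adjusted p = 0.0373, and adjusted p = 0.201 with an estimated correlation), with IER3 at 2.06 and SPRY1 at 0.82, against ETV4 at -0.99 and ETV5 at -0.85. TGF-beta and Nodal targets did not pass (2 rose and 1 fell of 13, 2 and 2 adjusted over the list alone, adjusted p = 0.542), with PMEPA1 at 0.83. Of 13 mesenchymal transition genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 1.23e-07), including CDH11 at 1.88, MMP9 at 1.59 and the fibronectin receptor subunit ITGA5 at 1.34. Beside them, of 15 stromal and fibroblast markers, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with COL5A1 at 1.54, PDGFRB at 1.51 and THY1 at -1.41. That list had adjusted p = 1.18e-04, and adjusted p = 0.213 with an estimated correlation. Epithelial markers did not pass (3 rose and 0 fell of 17, 4 and 0 adjusted over the list alone, adjusted p = 0.135), with DSP at 1.13.

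Interferon response genes were lower at day 2, with 8 falls and 0 rises among 25 (10 and 0 adjusted over the list alone, median -0.46, or -0.12 with undetected genes set at the detection level, adjusted p = 3.42e-07). Besides the IFIT genes, DHX58 was undetected in knockdown arrays and at least 1.15-fold lower (adjusted p = 0.00152). DNA replication genes had 1 fall and 0 rises of 31 (0 and 0 adjusted over the list alone, adjusted p = 0.0305, and adjusted p = 0.328 with an estimated correlation), the fall being that of MCM2 (-0.53, adjusted p = 0.0423), which was lost without any 1 of the 6 day 2 arrays, control day 3 replicate 1 or 2 or knockdown day 3 replicate 3 (adjusted p = 0.0502 to 0.137). The MCM2 call was also lost with median scaling (adjusted p = 0.061). Mitosis genes did not pass (0 of 35 over all genes and adjusted over the list alone, adjusted p = 0.41). Among them TOP2A passed in 5 of 21 alternatives (higher, adjusted p = 0.0158 to 0.204) and AURKA in 2 (lower, 0.0415 to 0.304), and TOP2A did so without knockdown day 3 replicate 1 (0.0499). Besides the exceptions given, the day 2 list calls named here held with an estimated correlation (adjusted p = 0.00517 to 0.0266). Groups of 3 arrays did not overlap for 24.1% of the 10506 genes, against 10% by chance. Without control day 2 replicate 1, 598 genes were called in place of 910.

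At day 3 the largest fitted rise was again that of CST1 (6.82, SE 0.48, adjusted p = 2.29e-07). ALPK2, a kinase gene, HAPLN1 and FGF17, an FGF ligand, were undetected in control arrays and lay at least 30.8-fold, at least 37.9-fold and at least 32.1-fold higher in knockdown (adjusted p = 3.26e-11, 2.11e-10 and 3.16e-09, n = 3 per group). WLS rose by 5.51 (SE 0.22, adjusted p = 1.36e-09), SOX17 by 5.38 (SE 0.27, adjusted p = 1.09e-08) and BMP2 by 5.33 (SE 0.20, adjusted p = 8.43e-10). Other probes gave smaller rises, 1.94 for HAPLN1 and 2.91 for WLS. LRAT fell by 2.82 (SE 0.22, adjusted p = 6.02e-07), and CLC, a galectin of eosinophils, was undetected in knockdown and at least 4.86-fold lower (adjusted p = 6.02e-07). In all, 3114 genes changed, 1505 higher and 1609 lower (1571 and 1222 with median scaling, 1696 and 1240 with the authors' log2 values, so which direction is more frequent depends on the scaling among other settings), and 1015 of them changed at least 2-fold (700 higher, 315 lower).

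DKK1 and MYL4, a myosin light chain gene, were undetected in control arrays and lay at least 16.5-fold and at least 10.9-fold higher, and EPSTI1 rose by 4.77. Further falls at day 3 were those of IFIT3 (-2.79), CAMKV (-2.78), the class II pseudogene HLA-DPB2 (-2.71), IFIT1 (-2.65), the glutamate receptor gene GRM4 (-2.62) and LNCPRESS1 (-2.48), and NPY5R was undetected in knockdown and at least 3.16-fold lower. NANOG fell by 1.94 (SE 0.18, adjusted p = 3.39e-06) and SOX2 by 1.77 (SE 0.26, adjusted p = 1.68e-04). GATA3, a trophoblast and amnion factor, was undetected in control arrays and at least 1.79-fold higher (adjusted p = 6.55e-04). TBXT, the brachyury gene of the primitive streak, was undetected in knockdown and at least 1.57-fold lower (adjusted p = 0.0118), a call lost without knockdown day 3 replicate 1 (adjusted p = 0.0554, range over the alternatives 0.0035 to 0.0554). GATA6 was detected on 2 of the 3 knockdown arrays of day 3 and on no other array.

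**Figure D2:**
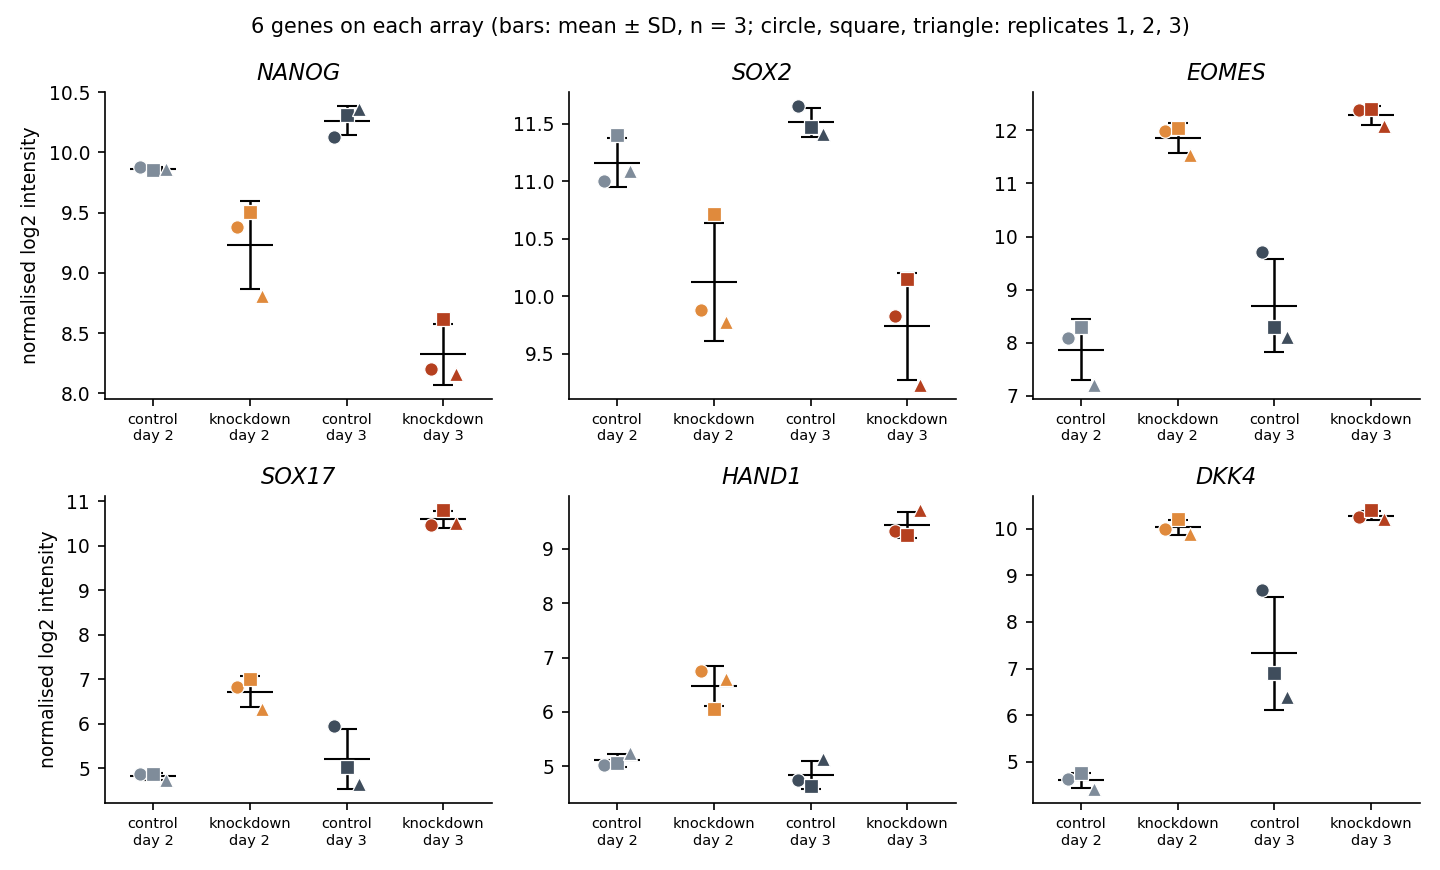
Normalised log2 intensity of 6 genes on each of the 12 arrays by group, with lines at group means and bars of 1 SD (n = 3), each panel on its own scale. SOX17 and HAND1 lie highest on the day 3 knockdown arrays, EOMES and DKK4 are high in knockdown on both days, and DKK4 spreads widely over the control arrays of day 3.

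Of the 39 pluripotency genes, 30 fell at day 3 and 1 rose (32 and 1 adjusted over the list alone, median -1.40, adjusted p = 1.25e-12). VSNL1 fell by 2.35, DPPA2 by 1.98 and SEPHS1 by 1.79, and OTX2 rose by 2.20. In the naive pluripotency list, 4 fell and 1 rose of 9 (5 and 1 adjusted over the list alone), with PRDM14 at -1.91, KLF4 at -1.31, DPPA5 at least 2.66-fold lower and TBX3 at least 1.25-fold higher. That list had adjusted p = 0.0266, and adjusted p = 0.0967 with an estimated correlation. It shares 3 measured genes with the pluripotency list, PRDM14 and DPPA5 among them, so the calls of these lists are not independent.

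Of 17 endoderm genes, 13 rose and 0 fell at day 3 (13 and 2 adjusted over the list alone, median 1.99, adjusted p = 1.65e-09), among them FLRT3 at 4.27, CER1 at 4.05 and DAB2 at 2.36. Of 18 mesoderm and primitive streak genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 2.29e-08), with LHX1 at 3.83, MSX1 at least 10.5-fold and GATA4, a factor of heart and endoderm, at least 1.81-fold higher. Of 18 measured trophoblast genes (49 on the array), 11 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 5.81e-07). HAND1 lay at least 11.4-fold, CCKBR at least 8.61-fold, ENPEP at least 7.04-fold and the iron exporter SLC40A1 at least 5.08-fold higher. Amnion markers had 5 rises and 3 falls of 10 (5 and 3 adjusted over the list alone), with IGFBP3 at 3.08, ISL1 at 2.21 and KRT7 at least 4.10-fold higher. That list had adjusted p = 0.0408, and adjusted p = 0.096 with an estimated correlation, and its call was lost with the authors' log2 values (adjusted p = 0.0642, range over the alternatives 0.0262 to 0.096). Neuroectoderm genes had 8 rises and 2 falls of 17 (8 and 3 adjusted over the list alone, adjusted p = 0.0367), with CDH2 at 1.53, MEIS2 at least 1.95-fold higher and FOXD3 at least 1.75-fold lower. That call was lost with the replicate block (adjusted p = 0.051, range over the alternatives 0.0262 to 0.112), and had adjusted p = 0.0876 with an estimated correlation. Between the days the neuroectoderm median changed by -0.36 in control and by 0.07 in knockdown arrays (camera adjusted p = 0.00112 and 0.536). The day 3 call thus came with a lower control level. The neuroectoderm list shares FOXD3 with the pluripotency list and CDH2 with the mesenchymal transition list.

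Of 14 BMP targets, 11 rose and 2 fell at day 3 (11 and 2 adjusted over the list alone, adjusted p = 2.94e-08), with ID3 at 3.05 and DLX5 at least 4.71-fold higher. Of 13 WNT targets, 8 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.78, adjusted p = 2.69e-06), with TNFRSF19 at 4.24, the WNT inhibitor SFRP1 at 2.26 and NKD1 at least 2.65-fold higher. FGF and ERK targets did not pass as a list (4 rose and 2 fell of 18, 5 and 2 adjusted over the list alone, adjusted p = 0.409), with IER3 at 3.71, CCND1 at 0.78, ETV4 at -1.51 and ETV5 at -1.22. TGF-beta and Nodal targets did not pass (4 rose and 3 fell of 13, 4 and 4 adjusted over the list alone, adjusted p = 0.425), with the activin antagonist FST at 1.27, PMEPA1 at 0.98 and LEFTY1 at -1.34. Of 13 mesenchymal transition genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 4.68e-08), with ITGA5 at 2.74, CDH11 at 2.44 and TWIST1 at 1.84. Beside them, 12 of 15 stromal and fibroblast markers rose and 1 fell (12 and 1 adjusted over the list alone), with COL5A1 at 3.01, COL1A1 at 2.59, LUM at least 1.02-fold higher and THY1 at -2.22. That list had adjusted p = 5.81e-07, and adjusted p = 0.0898 with an estimated correlation. Epithelial markers had 5 rises and 0 falls of 17 (5 and 0 adjusted over the list alone, adjusted p = 0.0231, and adjusted p = 0.318 with an estimated correlation), with KRT19 at 2.16, KRT8 at 1.70 and DSP at 1.23.

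**Figure D3:**
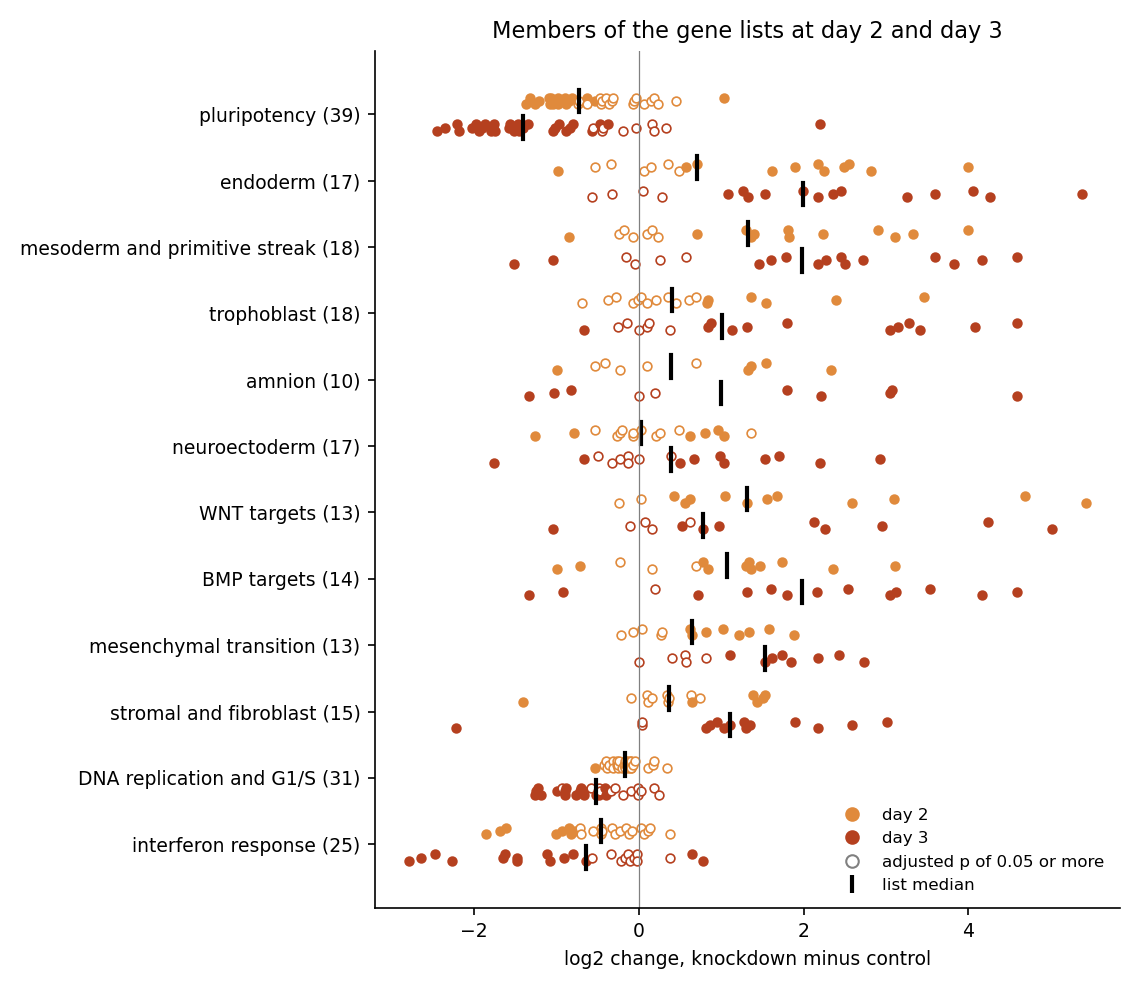
Fitted log2 change (knockdown minus control) of each measured member of 12 lists at day 2 and day 3, with filled points at an adjusted p under 0.05, list medians as bars and the number of members in brackets. The pluripotency medians lie at -0.72 and -1.40 and the endoderm medians at 0.70 and 1.99.

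Of 31 DNA replication genes, 17 fell and 0 rose at day 3 (17 and 0 adjusted over the list alone, adjusted p = 6.29e-06, and adjusted p = 0.0616 with an estimated correlation). DTL fell by 1.27, PRIM1, a primase subunit, by 1.25, and the helicase genes MCM2 and MCM3 by 1.19 and 0.89. Of 35 mitosis genes, 8 fell and 0 rose (7 and 0 adjusted over the list alone, adjusted p = 0.0391, and adjusted p = 0.215 with an estimated correlation), with AURKA at -0.61. Of 25 interferon response genes, 13 fell and 2 rose (13 and 2 adjusted over the list alone, median -0.65, adjusted p = 3.08e-05), with IFIT2 at -2.47 and OAS2 undetected in knockdown and at least 2.44-fold lower. Besides the exceptions given, the day 3 list calls named here held with an estimated correlation (adjusted p = 0.00598 to 0.0339). With undetected genes set at the detection level, list medians moved toward 0, for mesoderm and primitive streak from 1.98 to 0.82, for trophoblast from 1.00 to 0.43, for endoderm from 1.99 to 1.53 and for interferon response from -0.65 to -0.57. Groups of 3 arrays did not overlap for 43.0% of genes, against 10% by chance.

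The knockdown effects of the 2 days went largely the same way. Of the 598 genes higher at day 2, 548 were also higher at day 3, where independent lists would share 85.7, and of the 312 lower genes 277 were also lower, where independent lists would share 47.8. Across genes, which are not independent replicates, the effects correlated at r = 0.826 and rho = 0.733. Among genes called at day 2, 453 of the 598 higher and 237 of the 312 lower had a larger effect at day 3, with a median ratio of 1.37.

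**Figure D4:**
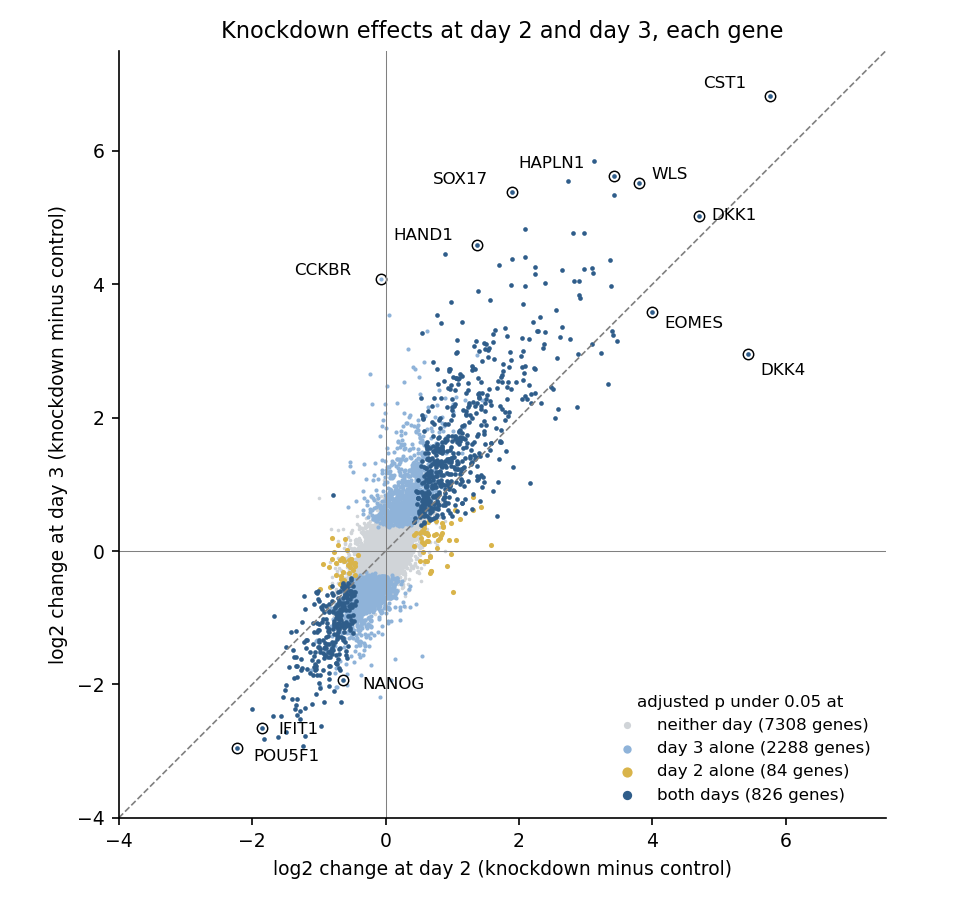
Fitted log2 change (knockdown minus control) of each of the 10506 genes at day 2 and at day 3, coloured by the day on which the gene was called, with a dashed line of equal change and circles at named genes. Most genes called on both days lie on the same side of 0 on both axes, and the correlation across genes is 0.826.

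The difference between the effects of the 2 days passed the test for 243 genes, 182 with the larger value at day 3 and 61 with the smaller. CCKBR, a gastrin receptor gene, and GRP, which encodes gastrin-releasing peptide, were detected on the 3 knockdown arrays of day 3 and on no other array (adjusted p = 1.49e-05 and 5.01e-06). SOX17 rose more at day 3 by 3.48 (SE 0.38, adjusted p = 2.41e-04), CCDC81 by 3.57 (SE 0.35, adjusted p = 7.31e-05) and HAND1 by 3.23 (SE 0.28, adjusted p = 3.09e-05), fitted values that count undetected control arrays at their own intensity. NANOG fell further at day 3 by 1.31 (adjusted p = 0.0155), and for SOX2 the further fall did not pass (-0.73, adjusted p = 0.455). The most negative differences that passed were those of FGF19 (-2.11, adjusted p = 0.002), DPPA5 (-2.11), TIMP4 (-1.76), CLC (-1.69) and DKK4 (-2.48, adjusted p = 0.0405). The DKK4 difference came with a higher control level at day 3, and its call was kept without control day 3 replicate 1 or 3 and lost in the other 10 fits that left out 1 array (adjusted p = 0.052 to 0.0957, over all alternatives 0.00257 to 0.137). The CLC call was lost without background correction (adjusted p = 0.0525, range over the alternatives 0.00173 to 0.0525).

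Of the lists, endoderm (median difference 0.60, or 0.55 with undetected genes set at the detection level, adjusted p = 2.03e-07), BMP targets (0.74, or 0.63, adjusted p = 8.56e-09) and trophoblast genes (0.48, or only 0.18, adjusted p = 1.42e-06) gained at day 3, and these held with an estimated correlation (adjusted p = 0.0298, 0.00938 and 0.00938). Of their members, 5, 3 and 3 rose further and 0 less (8, 7 and 4 adjusted over the list alone). Pluripotency genes (-0.53, 4 lower and 1 higher, 15 and 1 adjusted over the list alone, adjusted p = 8.56e-09) had adjusted p = 0.0541 with an estimated correlation, as had mesoderm and primitive streak, mesenchymal transition, DNA replication and mitosis genes. Interferon response and naive pluripotency (adjusted p = 0.126 with an estimated correlation), stromal markers (0.119), amnion (0.0869) and neuroectoderm genes (0.0525) lost the call likewise. WNT targets did not pass (-0.34, 1 higher and 3 lower of 13, 2 and 3 adjusted over the list alone, adjusted p = 0.22). The count of 243 fell to 154 without knockdown day 3 replicate 1 and to 80 among genes detected on all 12 arrays, and was 402 with array weights and 756 with the replicate block.

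Averaged over both days, 3425 genes changed, 1629 higher and 1796 lower (1721 and 1354 with median scaling, 1822 and 1396 with the authors' log2 values), 626 of them at least 2-fold.

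In the control arrays, 26 genes changed between day 2 and day 3, 12 higher and 14 lower at day 3. OR52A1, an olfactory receptor gene, was undetected at day 2 and at least 1.79-fold higher at day 3 (adjusted p = 0.00447), and NPY5R rose by 1.12 (SE 0.14, adjusted p = 0.00456). DLK2 fell by 1.47 (SE 0.17, adjusted p = 0.00447). DKK4 (at least 2.70-fold higher), SULF1 (1.38), OAS2 (1.27), ACTC1 (-1.48), NPTX1 (-1.47), RNU6ATAC (-1.37) and LHX3 (at least 1.68-fold lower) passed too. The calls of DKK4, SULF1, ACTC1, NPTX1, RNU6ATAC and LHX3 were lost without control day 2 replicate 1 (adjusted p = 0.0561 to 0.0702), those of DKK4, OAS2, ACTC1 and RNU6ATAC without replicate 2 (0.0672 to 0.152), and those of all but LHX3 without replicate 3 (0.0761 to 0.155). Those of SULF1, OAS2, ACTC1 and RNU6ATAC were lost without control day 3 replicate 2 (0.0842 to 0.173), those of OAS2 and ACTC1 without replicate 1 (0.075 and 0.108), and that of RNU6ATAC without replicate 3 (0.116) and without knockdown day 2 replicate 1 or knockdown day 3 replicate 1 or 2 (0.0511 to 0.0633).

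Interferon response genes were higher at day 3 in the control arrays (2 rose and 0 fell of 25, 11 and 0 adjusted over the list alone, median 0.43, adjusted p = 4.89e-11). Cholesterol synthesis genes were higher too (0 of 16 rose, 1 adjusted over the list alone, median 0.27, adjusted p = 5.57e-04), and neuroectoderm genes were lower (0 rose and 1 fell of 17, 0 and 6 adjusted over the list alone, median -0.36, adjusted p = 0.00112). These held with an estimated correlation (adjusted p = 0.0179, 0.0286 and 0.0305). Pluripotency genes (higher, adjusted p = 7.73e-04), mesenchymal transition genes (lower, 0.00474) and the unfolded protein response (lower, 0.00197) passed only with the preset correlation, with adjusted p = 0.339, 0.339 and 0.269 with an estimated correlation. The other 18 lists did not pass (smallest adjusted p = 0.0583). With the replicate block 450 genes were called in place of 26. Without control day 2 replicate 1, 2 or 3 the count was 5, 10 or 7, without control day 3 replicate 2 it was 10, without knockdown day 2 replicate 2 it was 54, and groups did not overlap for 16% of genes, against 10% by chance.

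**Figure D5:**
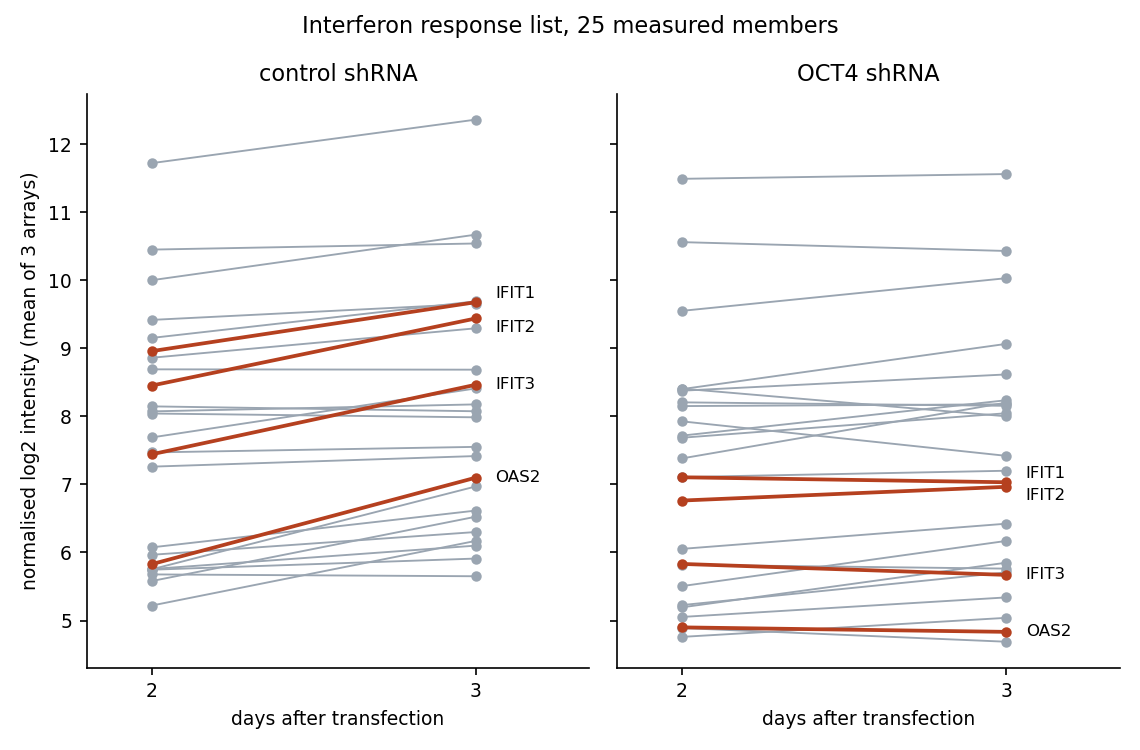
Mean normalised log2 intensity (3 arrays per point) of the 25 measured interferon response genes at day 2 and day 3 in the control and in the OCT4 shRNA arrays, with 4 genes drawn in red and labelled. In the control arrays 21 of the 25 lie higher at day 3 than at day 2, and in the knockdown arrays 16 do.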

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

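Of the tests in this part, the fit with replicate 3 as a batch term and the splits that part all pairs were chosen only after the result was seen. GJA4 was singled out after its values were seen, as were the genes of the second paragraph, which had been named for their day 3 effect and not for the difference. All differences below are fitted log2 values, day 3 effect less day 2 effect, and for genes undetected in a group they are no bounds on the fold.

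The test of the difference between the effects of the 2 days picked out 243 genes. Its largest positive values belonged to CCKBR (4.14), CCDC81 (3.57), GRP (3.49), SOX17 (3.48) and HAND1 (3.23), and its most negative to DKK4 (-2.48), FGF19 (-2.11), DPPA5 (-2.11), TIMP4 (-1.76) and CLC (-1.69). Among genes named for day 3, the difference also passed for FGF17 (2.82), MYL4 (2.74), ALPK2 (2.72), HAPLN1 (2.20), EPSTI1 (1.96), BMP2 (1.91) and WLS (1.72), whose rises were larger at day 3. It passed for GRM4 (-1.65), NANOG (-1.31) and NPY5R (-1.24), whose falls were larger at day 3. NPY5R was undetected in knockdown arrays on both days and rose in the control arrays, so its difference came from the control level. The DKK4 call passed in 6 of 20 alternatives (adjusted p = 0.00257 to 0.137) the fewest among the 10 genes named first. For the difference of the other 10 genes no alternatives were run.

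In all 3 lists passed the same test with an estimated correlation, with median differences of 0.48 for trophoblast genes, 0.60 for endoderm genes and 0.74 for BMP targets. With undetected genes set at the detection level these were 0.18, 0.55 and 0.63. The trophoblast list shares 3 measured genes with the BMP targets, HAND1 among them, so these are not independent. Exactly 1 gene was called in opposite directions on the 2 days. This was GJA4, a gap junction gene, at -0.78 at day 2 (adjusted p = 0.0042) and 0.84 at day 3 (adjusted p = 7.83e-04), a difference of 1.62 (adjusted p = 8.01e-04).

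For the difference between days, 100 of 200 possible splits were drawn that reassigned the days within each arm. Of these 3 gave as many genes as the real split, itself included. The 2 others called up to 1128 genes, several times the real 243, which points to a structure of the samples. Both put the 2 replicate 3 arrays of the control arm into 1 day and those of the knockdown arm into the other, as 8 of the drawn splits did, and the highest count of a drawn split without that arrangement was 238. Since the numbers pair the days within each arm, the real split was also set against the 32 splits that part all these pairs. Of these 2 gave as many, the real one included (6.25%), a share that does not exclude chance at 0.05. The other, with 536 genes, exchanged the days of 1 arm entirely and so measures a change with time shared by both arms, and the highest count besides it was 178. With the replicate number as a block the real contrast called 756 genes, and with replicate 3 as a batch term 702.

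Kept probes for which the annotation names no gene stand outside the comparisons of the report. Of 2060 such probes, 125 changed with knockdown at day 2 (70 higher, 55 lower) and 475 at day 3 (209 higher, 266 lower), while 4 changed between days in the control arrays. Which transcripts they measure was not analysed here.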

How the results depend on the processing

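The fits with replicates 1 and 2 only and with replicate 3 as a batch term were tests chosen after the results were seen. The chip block was not run.

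The number of genes changed at day 2 (910) was 1815 with the replicate block, 1739 with replicate 3 as a batch term, 359 at a change of at least 2-fold and 478 at an adjusted p under 0.01. Leaving out 1 array gave 598 (without control day 2 replicate 1) to 953 (without knockdown day 3 replicate 3), and the other settings 616 to 1279. At day 3 (3114 genes) the counts were 1015 at a change of at least 2-fold and 1937 at an adjusted p under 0.01. The replicate block gave 4536, leaving out 1 array 2372 to 3249, and the other settings 2442 to 4469. The higher genes outnumbered the lower at day 3 with median scaling, the authors' log2 values, replicates 1 and 2 only, an adjusted p under 0.01, a change of at least 2-fold, and without control day 3 replicate 2 or 3 or knockdown day 3 replicate 1 or 2. The 2 stricter thresholds lower a count by construction. The count averaged over both days (3425) was 626 at a change of at least 2-fold and 2206 at an adjusted p under 0.01. It stayed within 1.5-fold under the other settings, with 4863 under the replicate block and 2924 to 3352 with 1 array left out.

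For the difference between days (243 genes) the count was 80 among genes detected on all 12 arrays, 756 with the replicate block, 402 with array weights, 702 with replicate 3 as a batch term, 103 at an adjusted p under 0.01 and 204 at a difference of at least 2-fold. Leaving out 1 array gave 154 (without knockdown day 3 replicate 1) to 259 (without knockdown day 2 replicate 3). For control day 3 against control day 2 (26 genes) it was 7 among genes detected on all 12 arrays, 450 with the replicate block, 166 with array weights, 10 with replicates 1 and 2 only, 349 with replicate 3 as a batch term, 5 at an adjusted p under 0.01 and 17 at a change of at least 2-fold. Leaving out 1 array gave 5 (without control day 2 replicate 1) to 54 (without knockdown day 2 replicate 2). Requiring detection on all arrays drops genes that are off in 1 group, and a block or batch term takes the spread between replicate numbers out of the error. At day 2 and over the 4 groups that enter the difference, not every pair of arrays with the same number correlated over 0.1 (lowest 0.022 and -0.00146), although the pairs within an arm did and 10 of the 12 arrays matched an array of their own number best. The cause of the other changes was not tested.

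The POU5F1 change stayed past the threshold under all alternatives. With 1 array left out it was -2.39 to -2.05 at day 2 (highest adjusted p = 9.29e-05) and -3.09 to -2.81 at day 3 (highest adjusted p = 2.41e-06). The correlation of effects between days was 0.788 to 0.836 over the alternatives.

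With an estimated correlation, 8 of 11 list calls held at day 2, 8 of 15 at day 3, 3 of 13 for the difference and 3 of 6 in the control. The cause of these losses was not tested. Over 8 settings and 24 lists in 4 comparisons, 699 of 768 list results kept direction and side of the threshold, 34 lost the call, 19 gained it, 16 uncalled ones changed direction and 0 called ones reversed. Among the list calls at day 3 and in the control, the replicate block removed 1, that of neuroectoderm at day 3.

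For the named genes, 4642 of 4845 results kept direction and side of the threshold, 163 lost the call, 36 gained it, 2 uncalled ones changed direction and 2 reversed. The reversed ones were KRT18 at day 3 (-0.25, adjusted p = 0.325) and CDKN1A at day 3 (-0.20, adjusted p = 0.471), both with another probe of the gene in place of the brightest, where neither passed the test. Of the 163 losses, 124 came from leaving out 1 array.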

Other observations

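Of the tests in this part, those of a further interferon fall in the knockdown arrays, of a construct response in the control arm, of a shared batch of replicate 3, both tests of the WNT list, and the replicate block for the knockdown arrays of the 2 days were chosen only after the result was seen. So were the genes named for replicate 3 and for disagreeing probes.

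Besides the TGF-beta and Nodal targets, 7 lists passed at neither day in the fit reported. Chromatin and DNA methylation genes had 4 falls and 0 rises of 22 at day 2 (4 and 0 adjusted over the list alone, adjusted p = 0.282). Without control day 2 replicate 3 or knockdown day 2 replicate 1, the day 2 calls of JARID2 and TET1 were lost (adjusted p = 0.0552 to 0.0662). The TET1 call was also lost without control day 2 replicate 1 (0.0863) or knockdown day 2 replicate 3 (0.0605), and another TET1 probe gave -0.51 (adjusted p = 0.0534). The JARID2 call was also lost without control day 2 replicate 2 (0.0545). At day 3 there were 4 falls and 1 rise (4 and 0 adjusted over the list alone, adjusted p = 0.0746), and the list passed with the authors' log2 values (0.0494) and without a detection filter (0.0387, range over the alternatives 0.0387 to 0.215). At day 3 the falls were those of PHC1 (-1.56), DNMT3B, a DNA methyltransferase (-1.5), TET1 (-1.05) and JARID2 (-1.02). Of 22 p53 targets, 0 changed at day 2 (0 adjusted over the list alone, adjusted p = 0.282), although the replicate block called TP53I3, DDB2 and TRIAP1 lower and GDF15 higher (adjusted p = 0.00461 to 0.0469), and the fit without knockdown day 3 replicate 3 called TP53I3 (0.0413) and DDB2 (0.0498). At day 3, 5 rose and 2 fell (5 and 3 adjusted over the list alone, adjusted p = 0.585), with GDF15 at 1.39 and GADD45A at 0.71. Their day 3 median was -0.05 and their mean 0.09. Of 19 genes of the unfolded protein response, 0 rose and 1 fell at day 2 (0 and 0 adjusted over the list alone, adjusted p = 0.572). This fall, CRELD2, was lost without control day 2 replicate 1 or 3, knockdown day 2 replicate 1 or 3, control day 3 replicate 1 or 2 or knockdown day 3 replicate 1 or 2 (adjusted p = 0.0505 to 0.17). Median scaling lost it too (0.0646). At day 3, 4 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.149, but 0.0387 without a detection filter, range over the alternatives 0.0387 to 0.426), with DNAJB9 at 0.89, ATF3 at 0.85 and EDEM1 at 0.69.

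Of 26 glycolysis and hypoxia genes, 1 rose and 0 fell at day 2 (1 and 0 adjusted over the list alone, adjusted p = 0.815). This rise, SLC2A3, was lost without control day 2 replicate 2 or 3 or knockdown day 2 replicate 1 or 3 (adjusted p = 0.056 to 0.102). At day 3, 6 rose and 4 fell (6 and 4 adjusted over the list alone, adjusted p = 0.585), with NDRG1 at 1.05 and BNIP3 at 0.85. The day 3 median was -0.04 and the mean 0.04. Of 27 oxidative phosphorylation genes, 0 changed at day 2 (0 adjusted over the list alone, adjusted p = 0.523), and COX5A, NDUFS3, UQCRB and SDHD fell at day 3 (0 adjusted over the list alone, adjusted p = 0.123, but 0.0262 without a detection filter, range over the alternatives 0.0262 to 0.266). All 4 calls were lost without control day 3 replicate 1 (adjusted p = 0.0516 to 0.168), and all but that of UQCRB without knockdown day 3 replicate 3 (0.0637 to 0.188). Those of UQCRB and SDHD were lost without control day 2 replicate 2, control day 3 replicate 2 or knockdown day 3 replicate 1 (0.0506 to 0.108). That of UQCRB was also lost without control day 3 replicate 3 or knockdown day 3 replicate 2 (0.0883 and 0.141). Median scaling (0.0863) and the mean of the gene's probes (0.109) lost it too, and another UQCRB probe gave -0.28 (adjusted p = 0.401). That of SDHD was also lost without control day 2 replicate 1 or 3 or knockdown day 2 replicate 1 (0.0565 to 0.0639). The authors' log2 values (0.0667), no detection filter (0.0763) and probes tested one by one (0.053) lost it too. Of 16 cholesterol synthesis genes, 1 rose and 0 fell on each day (1 and 0 adjusted over the list alone, adjusted p = 0.572 and 0.425), the riser being MSMO1 (0.84 at day 3). Its day 2 call was lost without any 1 of the 6 day 2 arrays or control day 3 replicate 2 (adjusted p = 0.0545 to 0.156). It was also lost with median scaling (0.0646) and with the mean of the gene's probes (0.0737), and another MSMO1 probe gave 0.35 (adjusted p = 0.427). The replicate block also called HMGCS1 (0.019) and INSIG1 (0.0476) higher at day 3. Between day 2 and day 3 this list was higher in the knockdown arrays too (median 0.28, adjusted p = 0.0209 with an estimated correlation, and 0.0357 with the replicate block added). Of 5 HOX genes, 0 changed on either day (0 rose and 1 fell at day 2 and 0 at day 3 adjusted over the list alone, adjusted p = 0.722 and 0.909), but HOXB6 was called lower on both days with the replicate block (adjusted p = 0.0226 and 0.0285) and without control day 3 replicate 3 (0.0316 and 0.0135).

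Within the knockdown arrays, 607 genes changed between day 2 and day 3, 411 higher and 196 lower. With the replicate block it was 1611, 837 higher and 774 lower. At day 3, 4 of 2373 genes with several kept probes had probes called in opposite directions: ARRB1, ATP2B4, METTL21A and RAB43.

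Interferon response genes were lower in knockdown at both days (list medians -0.46 and -0.65, or -0.12 and -0.57 with undetected genes set at the detection level). The day 3 median was no higher than -0.48 under 3 other preparations of the values and -0.55 with any 1 of the 6 day 3 arrays left out, which argues against the preparation or 1 array as the cause of the day 3 value. Between the days the list median changed by 0.20 in knockdown arrays (SD of the 25 members 0.351) and by 0.43 in control arrays. In knockdown arrays 16 of the 25 members lay higher at day 3, and 2 were called higher and 0 lower. Camera gave a rise there (adjusted p = 0.0283, and 0.206 with an estimated correlation). The list median thus did not fall further in knockdown arrays. Its change lay within the SD of the members, so the test does not decide on a further fall, and small falls of single members stay open. A response of the control arm to its construct, a different response to the 2 shRNA sequences, and an effect of OCT4 loss cannot be told apart. No untransfected arrays were part of the design to set the level without a construct. The labels name no other OCT4 shRNA that could separate a response to its sequence from OCT4 loss. Any of them could underlie the pattern.

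The replicate 3 array of each group stood apart, with 3630 of 10506 genes shifted against replicates 1 and 2 (1951 higher, 1679 lower, 42 at least 2-fold), among them RNF19B (1.69) and HNRNPA3 (-1.5). Of these genes, limma called 0 whose knockdown effect differed in replicate 3 (327 of all genes at an unadjusted p under 0.05). That test has less power than the test of the shift, with 1 replicate 3 array per group, so differing effects are not excluded. The shift correlated at 0.799 between the arms and so appeared in control arrays too, which argues against a different response to the knockdown as its main source. A curve of brightness explained 0.303% of the shift's variance. Quantile normalisation gives every array the same distribution of values and would remove such a shift beforehand. This value therefore cannot decide on a scanning or scaling difference that depends on brightness. The lowest correlation among pairs of replicate 3 arrays was 0.615, as a batch of culture, labelling or hybridisation might give. No batch is given in the sources used here, and a shared culture would look alike, so these cannot be told apart.

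WNT targets did not gain between the days as other risen genes did, with a median gain of -0.34 for the 11 members that had risen at day 2 and a larger effect at day 3 for 5 of them. Of 10000 random sets matched for brightness from 587 other risen genes, 0.03% had a median gain as low (random median 0.38, 5th percentile 0.05). The sets drew genes independently, although the list's estimated correlation between genes was 0.125, and were not matched for the size of the day 2 rise. This share alone therefore does not exclude a uniform growth of all early effects. The median day 3 level of the 11 members in knockdown was 10.08, against 15.56 for the brightest probe, which argues against a ceiling of bright probes. No biological explanation was tested. The list's difference between days did not pass its own test (adjusted p = 0.22), so this is a hypothesis.

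Regrouping the arrays gave these limits. For day 2, 1 of the 10 splits of the 6 arrays, the real one, gave as many genes (910, highest other 0). For day 3 it was 1 of 10 (3114, highest other 0) and for the control arrays of the 2 days 1 of 10 (26, highest other 0), and in both the 4 splits that part all pairs also gave 0 apart from the real one. These splits are too few for a share under 0.05. For the average over both days, 1 of 100 drawn splits within the days, the real one, gave as many (3425, highest other 1719). This share is under 0.05 only if the arrays of a day are exchangeable. The drawn splits did not regard the pairs by replicate number, and splits that part all pairs were not run for the average. Chance is therefore not excluded for paired arrays.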
